A study of Caenorhabditis elegans with 2 samples.

How the data were processed

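The series holds ChIP-seq of the C34B4.2 gene product of Caenorhabditis elegans, fused at its C terminus to GFP and FLAG, per the labels. The descriptions of the samples say that the immunoprecipitation used an antibody against GFP, while their antibody label names C34B4.2. The descriptions were followed here. ChIP-seq sequences the DNA that is crosslinked to a protein, and a peak is a place where such fragments pile up. The animals were whole L1 larvae of mixed sex, collected 6 h after synchronization by starvation following bleaching. Chromatin was broken by sonication, per the labels. There were 2 biological replicates of 1 group and no second group, so no comparison between groups was made.

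For each replicate and for both replicates pooled, the authors deposited a list of 30000 candidate peaks and background regions made as input for the irreproducible discovery rate (IDR) method, which keeps peaks whose rank is repeatable between replicates. They also deposited one IDR-thresholded list for the whole series. Each list exists for the ce10 and the ce11 genome build, per the descriptions deposited beside the lists. Those descriptions also name a control library behind each candidate list. The aligner, the peak caller, the IDR threshold and the scale of the peak signal are not given in the sources used here. Each peak carries a signal value, deposited by the authors and never negative, whose depth normalization is unknown. The deposited −log10 q per peak, named after the peak format, was only summarised and entered no test. The other column used is the deposited offset of the summit from the peak start, in bases. Signal values are the authors' own and were used to rank, filter or describe peaks, to compare peaks between the replicates, and to compare peaks with and without a 6-mer inside the IDR-thresholded list. Read depth is unknown for both replicates, so the precision of single signal values could not be given. All intervals for shares are Wilson intervals at 95% and cover counting error only.

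The ce11 lists were the main data. The chromosome names of the ce11 lists matched the WBcel235 assembly, which is the same sequence as ce11, and 0 peaks ran past a chromosome end. Genes came from Ensembl release 115. The mitochondrial genome was left out. The 267 thresholded peaks were ranks 1 to 267 of the pooled candidate list, so the list amounts to a threshold on pooled signal. In 39 of them the peak was narrower than 370 bp. Candidate summits lay on the identical base in both replicates for 179 of 30000 candidates (0.597%), so the 2 lists were counted as 2 replicates.

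Replicate agreement was Spearman's rho and Pearson's r of log2 signal over thresholded peaks, with each replicate's own overlapping candidate peak and a two-sided permutation test of 100000 resamples. Peaks, not animals, are the units of that test. Shared top peaks were the strongest 267 candidates of replicate 1 with a summit within 100 bp of one of the strongest 267 of replicate 2. Chance values came from 1000 circular shifts of the summits along each chromosome, one-sided for shared peaks and small RNA genes and two-sided for promoters. The promoter window ran from 1000 bp upstream to 200 bp downstream of any annotated transcript start of a protein-coding gene. Many worm messages are trans-spliced, so an annotated start can be a splice site downstream of the true start. The X chromosome was tested with a two-sided exact binomial test against its share of the nuclear genome. Gene lists were tested with two-sided Fisher's exact tests against all other protein-coding nuclear genes, with Benjamini-Hochberg adjustment over 30 lists. Classes of small RNA genes were tested within 200 bp, with adjustment over the classes. For 6-mers, windows of 50 bp to either side of the summit were compared with 2 windows centred 300 bp away from the same summit, by two-sided Fisher's exact tests adjusted over 2080 6-mers, each counted with its reverse complement. Windows of 20 kb around the C34B4.2 and unc-119 genes were compared with 10000 random positions.

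The gene lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule names C34B4.2 and unc-119, the genes at the 20 strongest thresholded peaks, the 3 strongest members of each enriched gene list or 2 of a depleted one, the 2 strongest members of each enriched small RNA class, and the 5 enriched 6-mers with the lowest p. At a top peak these are all protein-coding or tRNA genes with the summit in the promoter window, or else the nearest such gene. Genes named outside the rule were chosen after their values were seen. The alternatives changed the genome build, the threshold, the windows, the background, the test, the merging of near summits and the replicate used.

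The procedures were tested on simulated data. With 267 random summits of which 6 were placed at proteasome promoters, the gene list test on 19973 genes recovered that list in 20 of 20 simulations, and without them it called 0 lists. With 8 summits placed at snRNA genes, that class was recovered in 20 of 20 simulations. With no effect, the promoter test passed 0.05 in 1 of 20 simulations. A 6-mer placed in 40 windows came out first in 5 of 5 simulations over 2080 6-mers, and 0 6-mers were called without it. All 100 planted shared peaks were found. The simulated summits lay at random over the genome, without the promoter position and raised GC content of the real ones. The simulations therefore do not give the rate of false calls among 6-mers and gene lists in these data. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. Control libraries and signal tracks were not analysed here.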

Results

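ChIP-seq signal of GFP-tagged C34B4.2 was mapped in L1 larvae of C. elegans in 2 biological replicates. The IDR-thresholded list held 267 peaks in the ce11 build. The signal of these peaks, in the authors' own unit, ran from 112 to 868 with a median of 153. Their deposited −log10 q ran only from 0.523 to 2.10. Signals of single peaks are those of the pooled list unless a replicate is named. Read depth is unknown for both replicates.

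Of the 20 strongest peaks, 7 lay in the promoter window of a respiratory chain, cytosolic ribosomal protein or heat shock gene, namely atp-2, atp-1, cox-5A, rpl-3, rpl-20, rpl-35 and hsp-60. The respiratory chain list, as named here, also holds ATP synthase subunits. The first peak, on chromosome III at 13462999 to 13463254, had a signal of 868 and its summit 35 bp upstream of ant-1.1, an adenine nucleotide translocator of the mitochondrial membrane. Its signal was 428 in replicate 1 and 437 in replicate 2. T27E9.2 and abcf-2 started on the other strand, with the same summit 544 and 890 bp upstream of them. The peak at atp-2, the beta subunit of the mitochondrial ATP synthase, had a signal of 791, and C34E10.10 and C34E10.12 shared its promoter. The peak at atp-1, the alpha subunit, had a signal of 659 with the summit 1 bp upstream of the annotated start, and mcrs-1 lay on the other side. Among ribosomal protein genes, rpl-3 had a peak of 707, rpl-20 and its neighbour Y17G9B.5 one of 654, and rpl-35 one of 575. The chaperonin gene cct-8 and its divergent neighbour Y55F3AR.2 shared a peak of 503. The chaperonin gene hsp-60 and Y22D7AL.10 shared one of 442. Further promoters among the 20 strongest peaks were those of Y82E9BR.3 (468), tasp-1 and K01G5.10 (462), cox-5A (430), cdc-48.1 (417), sec-61.G and F32D8.13 (397), ubc-9 (385), and tag-340 and nhl-2 (357).

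Among these 20 peaks, 15 had a gene with the summit in its promoter window and 5 did not. The second strongest peak, with a signal of 823 on chromosome V at 1151379 to 1151652, lay 4756 bp upstream of the nearest gene, the calmodulin gene cmd-1. The peak nearest to gldi-3 (476) lay 2900 bp upstream of it, and the one nearest to T04C4.3 (394) lay 2746 bp upstream. The remaining peaks were nearest to tat-3 (384), at 10381 bp from its start on chromosome III, and to F58D12.1 (362), at 5641 bp from its start on chromosome V. Both of these lay beyond the end of the gene.

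The replicates ranked the thresholded peaks in a similar order. Of 267 peaks, 265 overlapped a candidate of replicate 1, 266 one of replicate 2, and 264 one of both. Over these 264 peaks Spearman's rho was 0.58 and Pearson's r of log2 signal was 0.71, each with a permutation p of 1e-05, the smallest that 100000 resamples can give. The log2 ratio of replicate 1 to replicate 2 had a median of 0.02 and an SD of 0.52. The peak upstream of eef-1A.1 and over cel-mir-5549, the last of the list with a signal of 112, had a value of 82.4 in replicate 1 and no overlapping candidate in replicate 2. Among 29733 candidates outside the list, of which 11709 occurred in both replicates, rho was 0.13. The list is the top of the pooled ranking, so the replicate signals of its weaker members are tied to their sum, and among the next 267 candidates rho was -0.58.

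Judged without the thresholded list, the 267 strongest candidates of the replicates shared 143 sites (53.6%, 95% interval 47.6 to 59.4%). Circular shifts gave 0.0682% on average and 1.12% at most, and the one-sided p of 0.001 was the smallest that 1000 shifts can give. Of the 267 thresholded peaks, 188 overlapped any of replicate 1's strongest 267 candidates, and 215 any of replicate 2's.

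**Figure D1:**
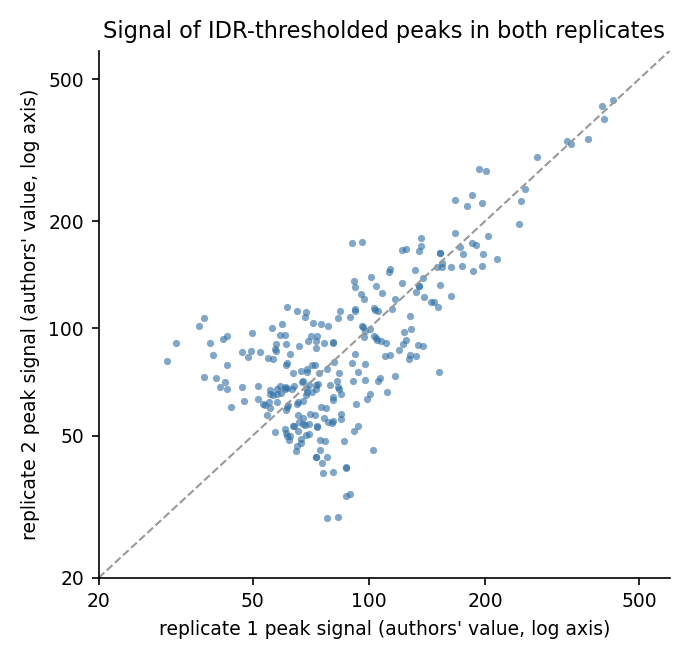
Signal of each thresholded peak's counterpart in replicate 1 (x axis) and replicate 2 (y axis), in the authors' unit on log axes, for the 264 peaks found in both; the dashed line marks equal values. The strongest peaks lie close to the line and the weaker ones scatter on both sides, with an SD of the log2 ratio of 0.52.

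Promoters of protein-coding genes held most of the summits. The summit lay in a promoter window at 196 of 267 peaks (73.4%, 95% interval 67.8 to 78.3%), against 26.1% on average and 35.2% at most over circular shifts. The two-sided p of 0.002 was the smallest possible. Outside protein-coding genes lay 199 summits (74.5%, against 34.9% after shifts), while introns held 38 (14.2% against 35.0%) and coding exons 19 (7.12% against 25.2%). A further 8 summits lay in 5′ UTRs and 3 in 3′ UTRs. The median summit was 169 bp upstream of the nearest protein-coding transcript start, given as -169 bp with quartiles of -341.5 and -14 bp. Upstream positions accounted for 206 summits, and 15 lay more than 5 kb from any protein-coding start, some of them next to small RNA genes such as cel-mir-52. Promoter windows on both strands, such as those of atp-1 and mcrs-1, shared the summit at 71 peaks (36.2% of the 196 in promoters). After shifts there were 6.79 on average and 18 at most. Shifted summits lay in any promoter window less often, so part of this contrast repeats the promoter excess above.

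**Figure D2:**
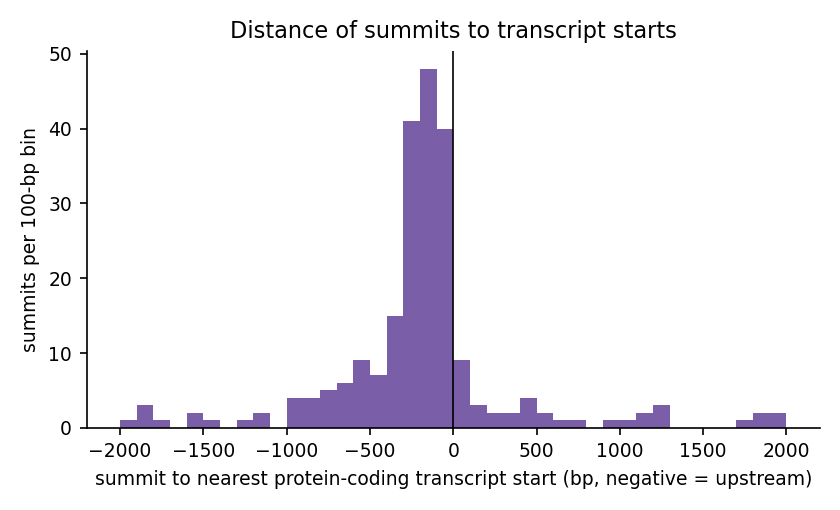
Number of thresholded summits (y axis, per 100-bp bin) by distance to the nearest protein-coding transcript start (x axis, bp, negative upstream), for the 226 summits within 2 kb. The counts peak just upstream of the start, around the median of -169 bp.

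Peaks were unevenly spread over the chromosomes. Chromosome III, which carries ant-1.1, atp-2 and rpl-3, held 70 peaks, or 5.08 per Mb with an exact Poisson interval of 3.96 to 6.42. Chromosome I followed with 3.78 per Mb, chromosomes II and IV held 2.75 and 2.74, and chromosome V held 1.53. The X chromosome held 18 peaks (6.74%, 95% interval 4.31 to 10.4%) against 17.7% of the genome's length, with an exact binomial p of 3.11e-07. One of the 18 was the peak at hsp-3, with a signal of 146. Among the candidates outside the list, 14.3% lay on X. The pooled candidates as a whole followed the same order of chromosomes, less steeply, from 368 per Mb on III to 240 on X.

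Genes for cytosolic ribosomal proteins, translation factors, respiratory chain subunits and heat shock proteins were hit more often than other genes. In all, 276 of 19973 protein-coding genes (1.38%) had a thresholded summit in the promoter window. Cytosolic ribosomal protein genes had one at 15 of 81 members (18.5%, 95% interval 11.6 to 28.3%), led by rpl-3, rpl-20 and rpl-35, with an odds ratio of 17.1 and a Fisher adjusted p of 9.45e-12. Respiratory chain genes had 6 of 41 (14.6%, interval 6.88 to 28.4%), led by atp-2, atp-1 and cox-5A, with an odds ratio of 12.5 and an adjusted p of 0.000198. The genes hit were the ATP synthase genes atp-2, atp-1 and atp-3 and the cytochrome c oxidase genes cox-5A, cox-5B and cox-6A. Heat shock protein genes had 4 of 22 (18.2%, interval 7.31 to 38.5%), with an odds ratio of 16.1 and an adjusted p of 0.00129. These were hsp-60 (442), the cytosolic chaperone genes hsp-90 (323) and hsp-1 (193), and the endoplasmic reticulum chaperone gene hsp-3. Translation factor genes had 5 of 40 (12.5%, interval 5.46 to 26.1%), led by eif-3.C (260), eef-2 and iff-2 (183), with an odds ratio of 10.4 and the same adjusted p of 0.00129.

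Chemoreceptor-type GPCR genes, a large worm family expressed mostly in sensory neurons, had a summit at 2 of 1309 members (0.153%, interval 0.0419 to 0.555%), sri-5 (197) and srh-2 (156). Their odds ratio was 0.103, with an adjusted p of 4.95e-05. Mitochondrial ribosomal protein genes, at 4 of 70 members, did not pass the adjustment (Fisher's exact test, adjusted p = 0.0802), and neither did nuclear hormone receptors, at 0 of 274 (adjusted p = 0.153). Other lists that did not pass were cell cycle and replication genes (2 of 39), proteasome subunits (1 of 33), splicing factors (1 of 40), germline genes (1 of 40), insulin, TOR and autophagy genes (1 of 37), histones (1 of 81) and F-box genes (3 of 322). No summit was found at the promoters of the tRNA synthetase, V-ATPase, collagen, C-type lectin, neuropeptide, insulin-like peptide, homeobox or bHLH lists. The lists for lipid metabolism, cytochrome P450, UDP-glucuronosyltransferases and glutathione S-transferases, and those for muscle, neurons, intestine and hypodermis, had none either. Of the 30 lists, 7 had an unadjusted p under 0.05. With only the 4461 genes whose promoter held a stronger candidate as background, the odds ratio of ribosomal proteins was 6.27, that of respiratory chain genes 6.62, and that of translation factors 4.52 with an adjusted p of 0.0578. The heat shock list had an adjusted p of 0.113 when each summit counted only for its nearest start, a setting chosen after seeing the data, and the GPCR list had 1 when circular shifts replaced Fisher's test.

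**Figure D3:**
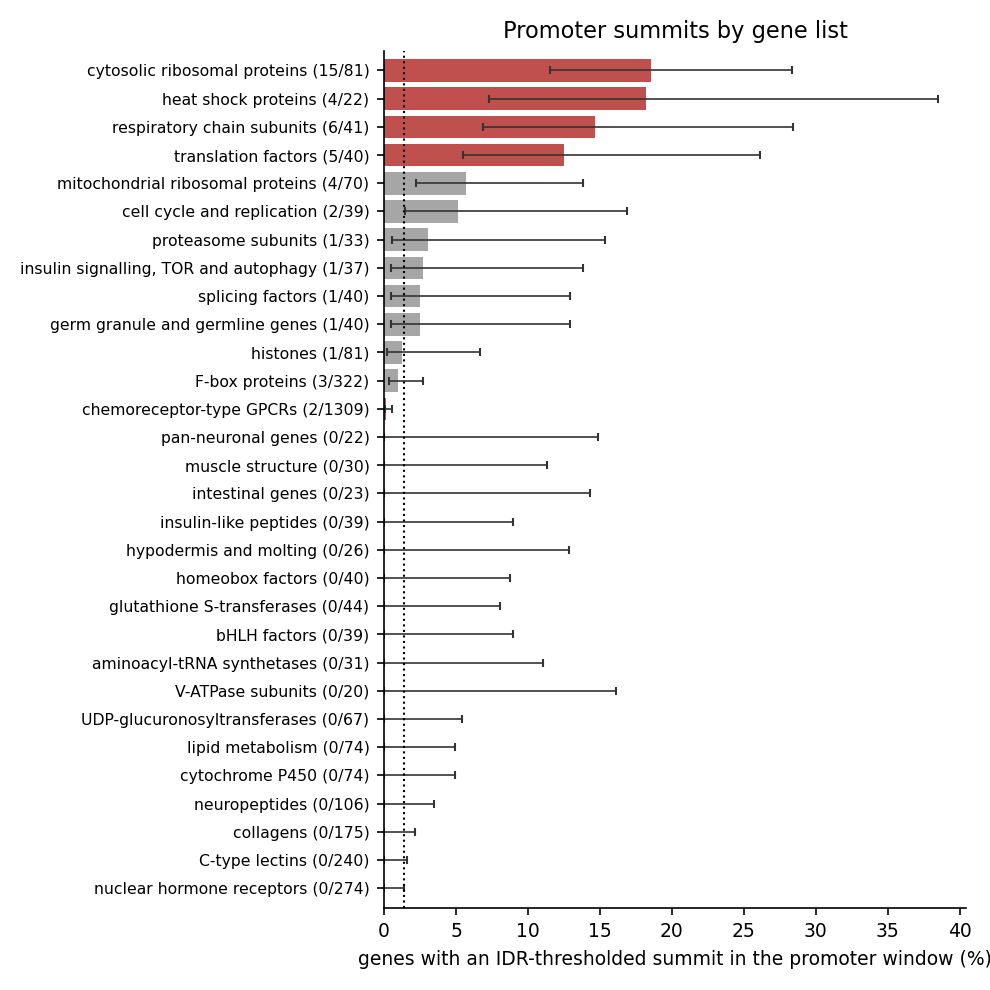
Percentage of each gene list's members with a thresholded summit in the promoter window (x axis), with hits and members in brackets, Wilson 95% intervals as lines and the 1.38% of all genes as a dotted line; red bars passed the adjusted p threshold of 0.05. The 4 enriched lists lie between 12.5% and 18.5%, and chemoreceptor-type GPCRs at 0.153%.

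Genes for small nuclear and nucleolar RNAs also lay close to peaks. Within 200 bp of an snRNA gene lay 10 summits, against 0.185 on average after shifts. They lay at 8 genes, since sls-2.4 and sup-6 had 2 summits each, and both summits of a gene had the same replicate signals. The strongest was at sls-2.4, a gene for the SL2 spliced leader RNA that is joined to messages of operons, with the summit 57 bp upstream, given as -57 bp, and a signal of 294. The next was at sup-6, annotated as an snRNA gene, with a signal of 266. Within 200 bp of snoRNA genes, whose RNAs guide the modification of ribosomal RNA, lay 11 summits against 0.562. They were led by Y53F4B.47 (277) and ZK994.7 (232). Within 200 bp of miRNA genes lay 4 summits against 0.287, led by cel-mir-52 (177) and cel-mir-2 (133). Each of these 3 classes had a one-sided p of 0.001, the smallest possible, and an adjusted p of 0.00133. None of the 612 tRNA genes had a summit within 200 bp, so 0 of 267 peaks fell there, which allows a share of up to 1.12%, and 0.596 summits came near one after shifts. The miRNA class fell to 1 summit, with an adjusted p of 0.346, in the strongest candidates of replicate 2 alone, and to 1 summit, with an adjusted p of 0.181, in the stronger part of the list.

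The sequence at the summits was rich in G and C and in words around ACGCAG and GACGCA. ACGCAG lay within 50 bp of 48 of 267 summits and in 6 of 534 flanking windows (1.12%), with an odds ratio of 18 and a Fisher adjusted p of 3.72e-15. GACGCA, which overlaps it, lay at 52 summits and in 9 flanks, with an odds ratio of 13.5. CGCGCA lay at 45 summits and 10 flanks, GCGCAC at 37 and 5, and GCGTCA at 39 and 9, with odds ratios of 10.2, 15.7 and 9.56. Over all 2080 6-mers, 251 were enriched and 148 depleted at an adjusted p under 0.05. Overlapping words are not independent, and summits had a higher GC content than flanks, at 48.8% ± 7.49 (SD, n = 267) against 36.7% ± 8.50 (SD, n = 534). With windows of 25 bp the enriched 6-mers numbered 147, and in the stronger part of the list 159. In the strongest candidates of replicate 1 alone, without replicate 2, the odds ratios of ACGCAG, GACGCA, GCGCAC and GCGTCA were 7.87, 5.92, 8.04 and 4.79, and in those of replicate 2 alone that of GACGCA was 21.2.

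**Figure D4:**
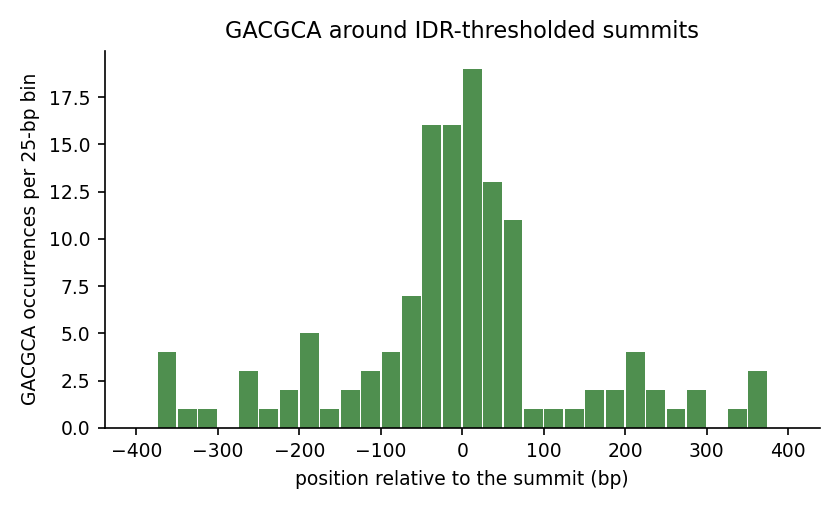
Occurrences of GACGCA or its reverse complement (y axis, per 25-bp bin) by position relative to the thresholded summit (x axis, bp), over 267 peaks. Within 50 bp of the summit lay 64 occurrences, and the remaining 65 were spread from 50 to 400 bp.

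The C34B4.2 gene and unc-119, a usual marker of such transgenes, were examined because extra copies in the strain can give signal without binding. The tagged gene C34B4.2, on chromosome V at 13083055 to 13090260, had 0 thresholded peaks within 20 kb and 3 candidates, against a median of 14 at random positions. Its best candidate ranked 14963 of 30000. The marker gene unc-119, on chromosome III at 10902641 to 10908935, had 0 thresholded peaks and 12 candidates. As many candidates or more lay in windows of the same size at a share of 0.991 of the random positions for C34B4.2 and 0.657 for unc-119. The best candidate near unc-119 ranked 1047, with a signal of 82.5. Within 10 kb of C34B4.2 lay 0 candidates, against a median of 8 at random positions. A control library stands behind each candidate list, and its strain is unknown here. If the control carries the same extra copies, their signal can be lost in peak calling, so the lack of peaks cannot exclude such copies.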

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

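The tests of broadly expressed genes, of promoter position and of neighbouring promoters were chosen after the results were seen, as was the look at peaks below the threshold.

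The candidates ranked just below the thresholded list also lay in promoters more often than chance. Among those ranked 268 to 534 in the pooled list, 112 summits lay in promoter windows (41.9%, 95% interval 36.2 to 47.9%), against 33.0% at most over 200 circular shifts. Among those ranked 535 to 801, 107 did (40.1%), against 31.5% at most, and among those ranked 802 to 1068, 99 did (37.1%), against 33.7% at most. From rank 1069 to rank 2670, in steps of 267 peaks, each share (28.1 to 33.7%) lay above the mean of its shifts (25.9 to 26.7%) and below their maximum, so the excess was smaller there and its end was not located. At ranks 268 to 534 and 535 to 801, ACGCAG lay at 19 and 18 of the summits (7.12% and 6.74%), and in 2.81% and 2.25% of their flanks. Cytosolic ribosomal protein genes numbered 4 and 3 there.

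The first pattern is the group of peaks at ribosomal protein, translation factor, respiratory chain and heat shock promoters, held by 30 of the 184 genes (16.3%, interval 11.7 to 22.3%). Over 1000 draws of genes with the same promoter GC, the share was 1.20% on average and 4.35% at most. The lists' mean promoter GC, 32.8%, was no higher than the 33.9% of other genes, so such draws could only give about the share of all genes. The lists had also been chosen for their summits. GC content at the summits themselves was not matched, so it stays open. Signal at all broadly expressed genes alike cannot be told apart from signal particular to these lists, because the test that shares differ over 10 lists of such genes (37 of 459 genes, permutation p = 0.00065) included those 4 lists, which had been chosen for their summits. Signal that follows the level of expression also stays open, because expression, the control library and an untagged strain were not analysed here. No biological explanation was tested, as there is only 1 group.

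The second pattern is a dispersed sequence, ACTCCTCTCGG, found within 100 bp of 16 thresholded summits and in 0 flanks. Of all 11-base words, it was picked for the largest excess of summits over flanks in these same peaks. Those counts therefore reflect how it was chosen. Among its peaks were those at F56G4.6 and wbp-4 (330) and at lig-4 and its neighbours cux-7 and C07H6.2 (257), named after their values were seen. Misplaced reads from repeats would need repeated sequence around the summits. At the median summit, however, 100% of the 36-base words within 100 bp occurred once in the genome, and the lowest summit had 75.9%. Only exact copies were counted, and the true read length is unknown. Promoter position alone would leave promoters with and without a copy alike. The 11-base word most enriched in odd-ranked peaks was GAGAGGAGTAC, which overlaps the first on the other strand, and even-ranked summits lay at 8 of 121 genes with a copy in the promoter window (6.61%), against 0.630% of other genes (Fisher p = 1.50e-06). Genes are the units of that test, and divergent neighbours can share a copy and a summit, so its p can be too small. The odd-ranked and even-ranked peaks are not fully separate either, as Y65A5A.2 had peaks with the first sequence in both. Other sequence next to the copies stays open, as does whether the tagged protein itself contacts these copies.

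The third pattern is the group of 21 summits near snRNA and snoRNA genes, such as sls-2.4 and Y53F4B.47. At these summits a median of 93.4% of 36-base words occurred once, below the 100% of all list peaks. The lowest of these summits had 65.1%, and the lowest of the whole list 20.5%. Only exact copies were counted and the true read length is unknown, so reads misplaced among similar copies stay open. Signal from neighbouring protein-coding promoters cannot be told apart from signal at the small RNA genes, because 15 of the 21 summits (71.4%, with an upper 95% bound of 86.2%) also lay in protein-coding promoter windows, close to the 73.4% of the whole list. The other 6 lay outside such windows.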

How the results depend on the processing

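Of 170 alternative values, 150 kept their direction and their side of the threshold, or stayed within 1.5 times for counts. The count for the nearest start only, the removal of peaks with the dispersed sequence and the use of candidates just below the list were chosen after seeing the data. The peaks numbered 134 in the stronger part of the list, which follows from how that part was made. There the enriched 6-mers fell to 159 and the depleted ones to 76, with fewer windows tested. With windows of 25 bp they were 147 and 70, since shorter windows hold fewer words. Among the candidates just below the list, 2 were enriched and 4 depleted, and the cause was not tested; ACGCAG had an odds ratio of 2.63 there (Fisher's exact test, adjusted p = 0.208). Removing summits near tRNA genes left out 0 peaks and so tested nothing. With circular shifts, 0 gene lists were depleted, as chemoreceptor-type GPCR genes had 3.16 hits by chance against 2 observed. Shifted summits lay in promoter windows at 26.1% on average, against 73.4% for the list. Chance hits at promoters are thus fewer than under Fisher's test, which can hide depletion and raise enrichment. The shifts also keep the number of peaks on each chromosome, which Fisher's test does not. Where the GPCR genes lie can therefore add to their depletion under Fisher's test, and the 2 differences were not tested apart. Within 10 kb of unc-119 lay 9 candidates against a median of 8 at random positions, a turn of direction in a count that passed no threshold in either window, and the cause was not tested. Mitochondrial ribosomal protein genes passed Fisher's exact test with the window of 500 bp (adjusted p = 0.0328) and with circular shifts (0.012), and cell cycle genes with the strongest candidates of replicate 1 alone (0.0077). With the strongest candidates of either replicate alone, 65.9 to 70.8% of summits lay in promoters, 8.24% lay on X in both, 4 to 5 gene lists were enriched and 1 depleted, 2 to 3 small RNA classes were enriched, 169 to 236 6-mers were enriched and 90 to 163 depleted. Without replicate 2, the depleted 6-mers were the 90, and the cause was not tested. Spearman's rho ran from 0.47 to 0.67 and the shared top peaks from 38.8 to 68.4% over their alternatives. Unknown read depth limits what can be said of peaks near the threshold. No paired analysis was possible because there is only 1 group.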

Other observations

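The test of GACGCA was chosen after the medians had been seen, and the range upstream of small RNA genes after the distances had been seen.

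Summits near small RNA genes gathered just upstream of their starts. Of 21 pairs of a summit and an snRNA or snoRNA gene, at 19 genes, 12 had the summit 10 to 70 bp upstream of the annotated start (57.1%), where an even spread over the searched window would put 11.7%. The median position was -29 bp. Among them were the SL2 RNA genes sls-2.4, sls-2.1, sls-2.8 and sls-2.2, with signals of 294, 256, 211 and 192, and the snoRNA genes Y53F4B.47 and ZK994.7. The range was chosen for these summits, so no p is given.

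The dispersed sequence ACTCCTCTCGG had 262 copies in the genome. Of the 126 copies in promoter windows, 18 had a thresholded summit within 100 bp, and of the 136 copies elsewhere 0 had one. The sequence had been chosen on these same peaks, most of which lay in promoters, so this contrast is no separate support. The peaks included those at hex-3 and fbxb-85 (186), W04C9.4 (174), cpn-3 (168) and mrt-2 (152), all named after their values were seen.

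A hypothesis was that peaks with GACGCA near the summit are stronger. The 52 thresholded peaks with GACGCA had a median signal of 199 and the 215 without it 147, a difference of 51.1 (permutation p = 0.00092, adjusted p = 0.0046 over the 5 named 6-mers). ACGCAG, which overlaps it, gave a difference of 31.2 (permutation test, adjusted p = 0.049), while GCGCAC, GCGTCA and CGCGCA gave 21.5, 5.93 and -4.79 and did not pass. As this was seen and tested on the same peaks, the p values give it no support of their own, and whether GACGCA goes with stronger signal stays open.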
